A study of Mus musculus with 16 samples.

How the data were processed

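Gene expression was measured by RNA sequencing in 16 libraries from 4 mouse acute myeloid leukaemias. Per the labels' protocols, RNA was extracted with Trizol, libraries were made from 400 ng of total RNA with an Illumina TruSeq V2 kit, and paired reads of 50 bases were sequenced on a HiSeq2500. The authors deposited raw counts per gene for each library and a table of the whole series, and the 16 single files held the same values as the table, with 0 cells differing. Per the submitters' processing notes, featureCounts and the build mm10 were used. The aligner, all versions, the strand setting and the treatment of reads that match several places are not given in the sources used here.

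The table held 27179 genes by their NCBI gene number, of which 25275 (93.0%) matched a symbol in the RefSeq gene table of assembly GRCm38.p6, the build also called mm10. Positions are those of that assembly. The genes without a symbol held 0.842% of the counts. Total counts per library ranged from 13457688 to 23042613, so that a gene at 1 CPM has 13 to 23 counts.

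Samples were grouped by treatment and day as the titles give them, with 4 libraries in each of 4 groups. The labels of doxycycline day 4 replicates 1 to 3 carry an added letter R that replicate 4 lacks, and its meaning is not given in the sources used here. The replicate number stands for the same leukaemia in all groups, per the labels, so the numbers pair the libraries. The deviations from the group means correlated between libraries of the same leukaemia by 0.189 to 0.684 and between those of different leukaemias by −0.377 to 0.0950, across genes, and each library's best match was its own leukaemia in 48 of 48 tests. The leukaemias come from separate animals, while each leukaemia and condition had a single culture. No libraries of a group agreed within sampling noise.

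Before the data were examined, the groups, tests, gene lists, alternatives and the rule for naming genes were fixed. The comparisons were doxycycline against untreated at day 2 and at day 4, the difference between these effects, and untreated day 4 against day 2. Counts of all 16 libraries were fitted in a single edgeR 4.0.16 quasi-likelihood model in R 4.3.3 with a coefficient per group, TMM factors and the gene filter filterByExpr (minimum count 10, minimum total 15), which kept 13273 genes. P-values were adjusted by the Benjamini-Hochberg method and genes called under 0.05. The biological coefficient of variation was 13.7%, with 12 residual degrees of freedom, or 9 with the leukaemia as a block. TMM factors ranged from 1.04 to 1.08 in untreated libraries, 0.984 to 1.03 with doxycycline at day 2 and 0.837 to 0.914 with doxycycline at day 4. CPM values are values computed from the deposited counts with these factors.

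Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, in both directions, with adjustment over the lists of a comparison and at least 5 tested members. All lists were also tested with fry, a rotation test of limma. The lists were MLL fusion targets, stem cell, granulocyte-monocyte progenitor, neutrophil maturation, monocyte and macrophage, dendritic cell, mitosis, DNA replication and ribosome biogenesis genes. Further lists were interferon response, MHC class II, MHC class I, p53 target, BCL2 family, and integrated stress response genes, then mitochondrial genome, nuclear oxidative phosphorylation, lysosome, cholesterol synthesis, RAS-ERK feedback and inflammatory cytokine and NF-kB genes. Marker lists covered T, B, NK, erythroid, platelet, basophil-eosinophil-mast and stromal cells. They were written from general knowledge, and leukaemic myeloid cells express many of the marker genes themselves.

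Genes named in every comparison were Kmt2a, Mllt3, Nras, Hoxa9, Meis1, Myb, Myc and Itgam. Beyond these, the 8 largest rises and 8 largest falls of each doxycycline comparison, and the 5 of each kind in the other comparisons, were taken among called genes with a mean log2 CPM of 3 or more and the same sign in all 4 leukaemias, leaving out unnamed gene models. Up to 4 called members of each list with the largest change were added. The mitochondrial genes given by their shared windows were chosen after their values were seen.

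The script was tested on simulated counts for 13273 genes with 200 changed genes. Of these it recovered 172 for the day 2 comparison, 176 for day 4 and 169 for untreated cells between the days, with 4, 15 and 9 false calls. At a change of 1.5-fold, 32, 35 and 30 of 50 were recovered, and at 4-fold 48, 50 and 50 of 50.

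For shared sequence, every 50-base window of each gene's GENCODE vM21 transcripts was looked up in transcripts from other chromosomes, which gave a value for 12036 (90.7%) of the tested genes. Copies that no transcript is annotated for were not searched. Alternatives were the leukaemia as a block, DESeq2 1.42.0, other scaling factors, library totals, no filter and a stricter filter. Others were only the groups compared, limma-voom with sample weights, a minimum change of 1.5-fold, and each library and each leukaemia left out in turn. Every way of dividing the 8 libraries of a comparison into 4 and 4 was tested as well (35 splits), and 100 draws for the difference between the days. Outlying libraries were looked for in total counts, TMM factors, genes with a count and the CPM of the genes named in every comparison or for a large change.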

Results

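RNA was sequenced from 4 primary acute myeloid leukaemias of mice, each taken from the spleen of a sick animal. The leukaemias were driven by MLL-AF9, a fusion of the proteins of the MLL (Kmt2a) and AF9 (Mllt3) genes. It was expressed from a Tet-Off vector that doxycycline switches off, together with an oncogenic NRAS from another vector. Cells of each leukaemia were grown in culture, untreated or with doxycycline at 1 µg/ml, and collected at day 2 and day 4. This gave 4 groups of 4 libraries, in which replicates 1 to 4 were the 4 leukaemias. Total counts per library ranged from 13457688 to 23042613, and 13273 of 27179 genes had enough counts to be tested. All 4 comparisons below used edgeR's quasi-likelihood test on these counts with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The ± values of log2 fold changes are standard errors derived from the F statistic of this test, with n = 4 libraries per group. Their spread was estimated over all 16 libraries and not only those compared.

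The counts of the fusion's partner genes followed the treatment in every library. Kmt2a (gene 214162, chromosome 9, 44803355 to 44881352 in mm10) lay at 11850 ± 1764 CPM (counts scaled by library size; SD, n = 4) in untreated cells and 143 ± 9.31 CPM with doxycycline at day 2. At day 4 it lay at 6705 ± 3370 CPM in untreated cells and 159 ± 19.9 CPM with doxycycline. Mllt3 (gene 70122, chromosome 4, 87769925 to 88033407) lay at 1830 ± 250.5 and 7.57 ± 0.889 CPM at day 2, and at 1030 ± 536 and 7.53 ± 0.674 CPM at day 4. The 4 untreated day 4 libraries were spread widely, with Kmt2a at 4772, 11047, 3430 and 7572 CPM in leukaemias 1 to 4. Nras (gene 18176, chromosome 3, 103058285 to 103067914) lay at 862 ± 108 CPM in untreated and 1395 ± 69.5 CPM in doxycycline cells at day 2. The counts of these 3 genes can hold reads of the vectors as well as of the mouse genes.

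**Figure D1:**
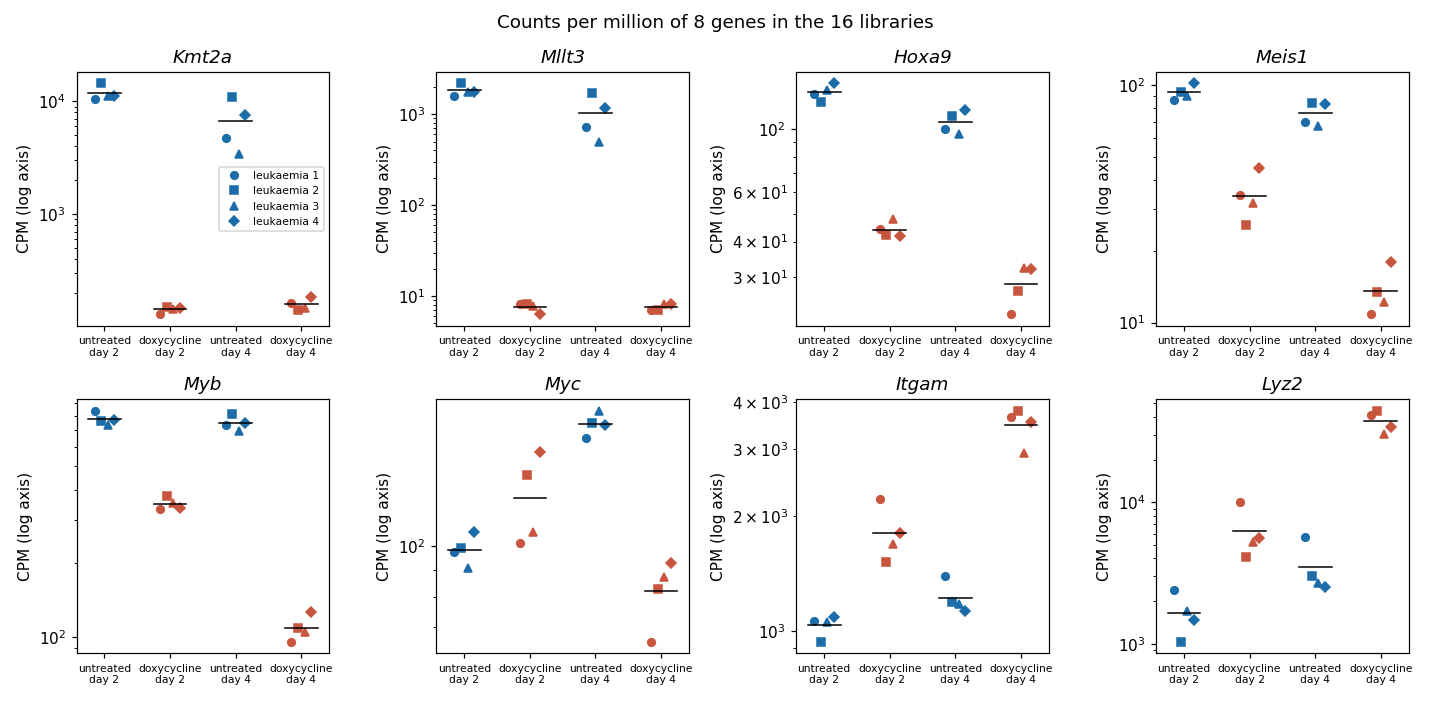
CPM (log axis) of 8 genes in the 16 libraries, by group, with 1 symbol per leukaemia and a line at the mean of each group of 4; blue is untreated and red is doxycycline. Kmt2a lay between 3430 and 14451 CPM in the 8 untreated libraries and between 129 and 185 CPM in the 8 doxycycline libraries.

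The day 2 comparison asked which genes changed within 2 days of doxycycline, which switches the fusion off. None of the 4 groups holds cells with doxycycline in which the fusion stays on. Loss of the fusion and an action of doxycycline itself therefore cannot be told apart for any change with doxycycline given here. Genes that MLL fusions are known to activate fell: of 23 tested members of the list of MLL fusion targets, 0 were higher, 18 lower and 5 not called. They included the homeobox genes Hoxa9 (−1.62 ± 0.10), Hoxa5 (−1.67 ± 0.14) and Hoxa6 (−1.63 ± 0.17), the homeobox cofactor Meis1 (−1.45 ± 0.15) and the receptor Flt3 (−2.56 ± 0.63). Of 30 neutrophil maturation genes, 20 were higher, 0 lower and 10 not called. Examples were S100a9 (3.37 ± 0.45), the iron-binding protein Lcn2 (3.22 ± 0.46) and the protease Mmp9 (3.17 ± 0.48). Of 31 monocyte and macrophage genes, 20 were higher and 0 lower, including the lysozymes Lyz2 (1.91 ± 0.32) and Lyz1 (1.81 ± 0.32). The calls of these 2 myeloid lists, given below, did not hold with an estimated correlation (adjusted p = 0.222 and 0.176).

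At day 2, 4380 genes were called, 2527 higher and 1853 lower with doxycycline, and 466 and 261 of these changed 2-fold or more. Kmt2a changed by −6.38 ± 0.32 (adjusted p = 1.11e-08) and Mllt3 by −7.91 ± 0.36 (adjusted p = 5.09e-09). Nras rose by 0.70 ± 0.10 (adjusted p = 8.69e-05). The transcription factor Myb fell by 1.15 on the log2 scale (adjusted p = 1.59e-07). Itgam, which encodes the myeloid integrin CD11b, rose by 0.81 ± 0.11 (adjusted p = 6.74e-05). Further large rises were those of the cystatin family genes Stfa2 (4.51 ± 0.59), Csta3 (4.45 ± 0.47), Stfa2l1 (3.25 ± 0.44) and Csta2 (3.09 ± 0.41). The complement receptor gene C5ar1 rose by 3.16 ± 0.31. The cystatin genes are close copies of each other, so the split of reads among them is uncertain. Large falls were those of Hspa2 (−4.14 ± 0.33), Skida1 (−3.48 ± 0.55), Bahcc1 (−1.90 ± 0.39), Hpgd (−1.82 ± 0.26) and Neto2 (−1.74 ± 0.21). All of these changed the same way in 4 of 4 leukaemias. Myc rose by 0.33 ± 0.12 (adjusted p = 0.0453). This call was lost without untreated replicate 1, 2 or 3 or doxycycline replicate 2 or 4, with an adjusted p of up to 0.157, and with library totals (0.153).

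Further lists had called members at day 2, and none of their list calls held with an estimated correlation (adjusted p from 0.176 to 0.781). DNA replication genes were lower in 30 of 35 and higher in 0, by small amounts, such as Mcm2 (−0.43 ± 0.06) and Rfc5 (−0.43 ± 0.06). Inflammatory cytokine and NF-kB genes were higher in 15 of 20 and lower in 1. They included the chemokine genes Cxcl2 (3.91 ± 0.55; 3.33 to 4.80 with single libraries left out) and Ccl4 (2.74 ± 0.46). Integrated stress response genes were higher in 18 of 25 and lower in 1, with Gdf15 (2.99 ± 0.49), Atf3 (1.89 ± 0.26) and Slc7a11 (1.62 ± 0.45). Cholesterol synthesis genes were higher in 15 of 20 and lower in 0, with Mvd (0.83 ± 0.09) and Fdft1 (0.78 ± 0.08). RAS-ERK feedback genes were higher in 8 of 16 and lower in 0, with Egr1 (1.92 ± 0.53) and Ier3 (1.89 ± 0.20). Of 23 p53 targets, 12 were higher and 1 lower, with Fas (1.14 ± 0.19). Of 15 BCL2 family genes, 9 were higher and 1 lower, with Bcl2l1 (0.92 ± 0.16). Lysosome genes were higher in 10 of 27 and lower in 0, with the cathepsin Ctsd (1.43 ± 0.23).

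The lists were tested against all other genes with camera. Adjusted p at day 2 was 4.82e-27 for MLL fusion targets, 1.40e-10 for neutrophil maturation, 3.06e-09 for monocyte and macrophage, 1.83e-12 for DNA replication and 2.37e-12 for inflammatory genes. It was 6.12e-07 for the integrated stress response, 4.26e-12 for cholesterol synthesis, 8.65e-05 for RAS-ERK feedback, 8.93e-04 for p53 targets, 0.0106 for the BCL2 family and 0.00878 for lysosome genes. With an estimated correlation the MLL fusion targets held (adjusted p = 0.00135), and the others did not. For neutrophil genes adjusted p = 0.222 with an estimated correlation, for monocyte 0.176, DNA replication 0.222, inflammatory 0.176 and stress response genes 0.208. For cholesterol synthesis it was 0.193, for RAS-ERK 0.222, p53 0.193, BCL2 0.222 and lysosome genes 0.781. Adjusted over the list alone, 20 fusion targets were lower, 24 neutrophil and 20 monocyte genes higher, and 32 replication genes lower. By the same adjustment 16 inflammatory, 18 stress response, 16 cholesterol, 10 RAS-ERK, 14 p53, 11 BCL2 family and 11 lysosome genes were higher.

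Calls of 4 other lists at day 2 were weak. Stem cell genes were lower in 3 of 10 (Kit, −1.35 ± 0.32), with an adjusted p of 0.0456 that was 0.0503 without leukaemia 1, 0.0747 without leukaemia 3 and 0.135 with library totals. Mitosis genes were lower in 2 of 26 (adjusted p = 0.0451; 0.104, 0.0786 and 0.0534 without leukaemia 1, 3 or 4). Ribosome biogenesis genes were lower in 5 of 28 (adjusted p = 0.0319; 0.184 and 0.0764 without leukaemia 1 or 4). Mitochondrial genome genes were higher in 4 of 13, with mt-Cytb at 0.58 ± 0.08 (adjusted p = 0.0158; 0.0615 without leukaemia 3). With an estimated correlation the adjusted p values of these 4 lists were 0.565, 0.885, 0.787 and 0.642. By fry the mitosis, ribosome biogenesis and lysosome lists were not called (adjusted p = 0.361, 0.148 and 0.0800). Adjusted over the list alone 3, 0, 4 and 5 members were called. No call was made for granulocyte-monocyte progenitor genes (1 higher and 3 lower of 15, adjusted p = 0.212), dendritic cell (3 and 1 of 6, 0.888), or interferon response genes (2 and 1 of 30, 0.166). The same held for MHC class II (1 and 1 of 9, 0.819), MHC class I (0 and 2 of 13, 0.681), nuclear oxidative phosphorylation (4 and 1 of 30, 0.819), platelet and megakaryocyte (0 and 1 of 5, 0.575) and basophil, eosinophil and mast cell genes (1 and 1 of 7, 0.889). Alternatives made calls of progenitor genes (adjusted p = 0.0232 without leukaemia 4) and interferon response genes (0.0139 without leukaemia 2 and 0.0313 with library totals). Of the markers of other cell types with under 5 tested members, 1 of 4 T cell genes was higher. Of the others, 1 of 2 erythroid genes was lower, and 0 of 3 B cell and 0 of 2 NK cell genes were called by edgeR. The 1 stromal gene, Pdgfrb, was lower (adjusted p = 0.0469), a call lost without untreated replicate 2, 3 or 4 or doxycycline replicate 1, 2 or 3 (up to 0.134) and with no filter (0.0520).

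**Figure D2:**
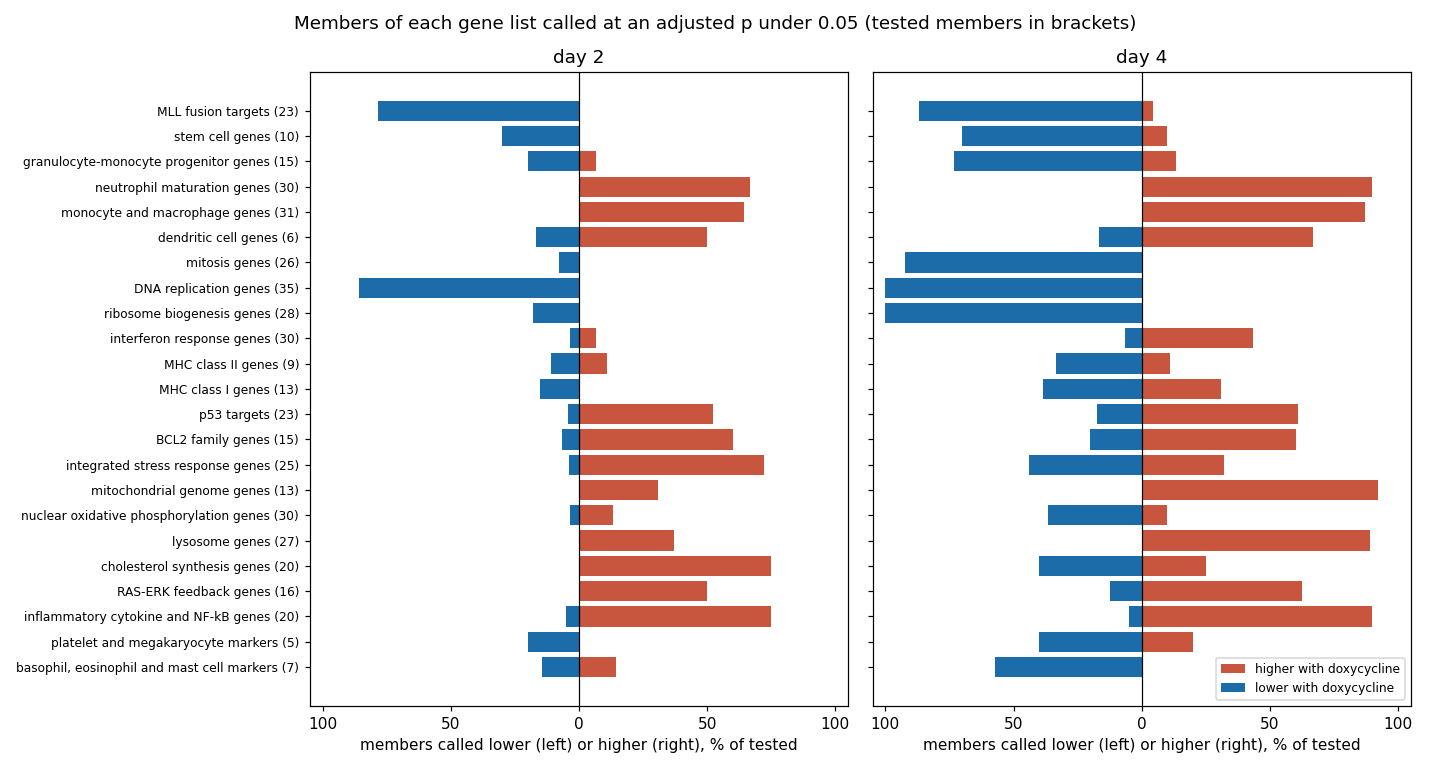
Share of the tested members of each gene list called higher (red, to the right) or lower (blue, to the left) with doxycycline at day 2 and day 4, in percent, with the number of tested members in brackets. At day 4, 35 of 35 DNA replication genes and 28 of 28 ribosome biogenesis genes were lower, while 27 of 30 neutrophil maturation genes were higher.

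At day 4 many neutrophil and monocyte genes were higher than in untreated cells, and genes of DNA replication, ribosome biogenesis and mitosis were lower. The calls of these 5 lists did not hold with an estimated correlation (adjusted p from 0.0819 to 0.653). Neutrophil maturation genes were higher in 27 of 30 and lower in 0. They included Mmp9 (4.80 ± 0.48), Ly6g (4.38 ± 0.44) and the formyl peptide receptor Fpr1 (4.16 ± 0.63). Monocyte and macrophage genes were higher in 27 of 31 and lower in 0, with the scavenger receptor Msr1 (3.66 ± 0.41). With single libraries left out, the change of Ly6g ranged from 4.10 to 5.17 and that of Fpr1 from 3.69 to 5.25. All 35 DNA replication genes and all 28 ribosome biogenesis genes were lower, with Cdc6 (−1.20 ± 0.07), Mcm2 (−1.17 ± 0.06) and Dkc1 (−1.45 ± 0.09). Mitosis genes were lower in 24 of 26, with Top2a (−0.71 ± 0.09). MLL fusion targets were lower in 20 of 23 and higher in 1, with Myb (−2.77 ± 0.08), Meis1 (−2.48 ± 0.16) and Flt3 (−3.70 ± 0.67).

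At day 4, 8723 genes were called, 4174 higher and 4549 lower, and 1405 and 857 of these changed 2-fold or more. The largest changes given next are those among genes with a mean log2 CPM of 3 or more. Kmt2a changed by −5.40 ± 0.30 (adjusted p = 2.36e-09), Mllt3 by −7.10 ± 0.35 (adjusted p = 7.43e-10) and Hoxa9 by −1.91 ± 0.10 (adjusted p = 1.76e-09). Myc was lower than in untreated cells by 1.06 on the log2 scale (adjusted p = 1.65e-06), and Itgam rose by 1.51 ± 0.11 (adjusted p = 2.27e-08). The level of Myc in untreated cells was itself higher at day 4, at 172 CPM beside 98.5 CPM at day 2. The aminopeptidase gene Anpep (4.75 ± 0.36), the chemokine gene Ccl6 (4.43 ± 0.52), Stfa2 (4.48 ± 0.56), Csta3 (4.36 ± 0.44), Slfn1 (3.96 ± 0.52) and Ifitm6 (3.87 ± 0.40) rose most among these beside Mmp9 and Lars2. With single libraries left out, Stfa2 ranged from 4.15 to 5.18 and Slfn1 from 3.67 to 4.80. Skida1 (−4.69 ± 0.64), the transcription factor gene Gfi1b (−4.47 ± 0.16), Hspa2 (−4.36 ± 0.34), the growth factor gene Angpt1 (−3.94 ± 0.31) and Il12a (−3.90 ± 0.32) fell most among these beside Mllt3 and Kmt2a. Lars2 rose by 4.04 ± 1.08 (adjusted p = 0.00371). The rise rested on doxycycline replicate 1, at 5068 CPM beside 88.8 to 119 CPM in the other 3. Its change was 0.37 without that library (adjusted p = 0.117), and its adjusted p was 0.0533 with the leukaemia as a block. Nras was higher by 0.25 ± 0.10 (adjusted p = 0.0311). The call was lost without untreated replicate 2, 3 or 4 or doxycycline replicate 1 or 4 (adjusted p of up to 0.110), and its change was −0.02 with library totals. Scaling by library totals, without TMM factors, moved the median of all genes by a similar amount, to −0.31 from −0.03. With it, 26.1% and not 47.9% of the called genes were higher at day 4. The same scaling gave 37.1% and not 57.7% higher at day 2, and changes are reported relative to the TMM scaling.

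Progenitor genes had members lower at day 4, and lysosome and mitochondrial genome genes had members higher. These 3 list calls did not hold with an estimated correlation (adjusted p = 0.0979, 0.328 and 0.426). Granulocyte-monocyte progenitor genes were lower in 11 of 15 and higher in 2, with Kit (−3.63 ± 0.37), and stem cell genes lower in 7 of 10 and higher in 1, with Hlf (−4.09 ± 1.33). Lysosome genes were higher in 24 of 27 and lower in 0, with Psap (2.82 ± 0.18) and the cathepsins Ctsb (2.75 ± 0.19) and Ctsd (2.69 ± 0.24). Mitochondrial genome genes were higher in 12 of 13 and lower in 0, with mt-Nd3 (1.19 ± 0.18) and mt-Co2 (1.11 ± 0.17), both of which share nearly all of their sequence with nuclear copies. Inflammatory genes were higher in 18 of 20 and lower in 1, with Cxcl2 (4.27 ± 0.44) and Ccl2 (3.78 ± 0.30). Of 23 p53 targets, 14 were higher and 4 lower, with Plk2 (2.90 ± 0.57) and Btg2 (1.74 ± 0.12). Of 15 BCL2 family genes, 9 were higher and 3 lower, with Bcl2l1 (1.55 ± 0.16).

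Camera at day 4 gave an adjusted p of 2.31e-12 for MLL fusion targets, 0.0105 for stem cell, 2.32e-04 for progenitor, 1.05e-07 for neutrophil and 1.26e-12 for monocyte genes. It was 6.11e-04 for mitosis, 1.66e-23 for DNA replication and 1.90e-22 for ribosome biogenesis genes. It was 0.0105 for p53 targets, 0.0314 for the BCL2 family (0.0509 without leukaemia 1), 0.00171 for mitochondrial genome, 1.35e-11 for lysosome and 8.17e-05 for inflammatory genes. That of stem cell genes was 0.0885 with library totals. With an estimated correlation the MLL fusion targets held (adjusted p = 0.0439) and the others did not. For stem cell genes adjusted p = 0.351 with an estimated correlation, and it was 0.0979 progenitor, 0.345 neutrophil, 0.0819 monocyte and 0.653 mitosis. The others were 0.0982 DNA replication, 0.0979 ribosome biogenesis, 0.324 p53, 0.345 BCL2, 0.426 mitochondrial genome, 0.328 lysosome and 0.345 inflammatory. Adjusted over the list alone, 28 monocyte and 27 neutrophil genes were higher, 25 mitosis genes were lower, and 20 fusion targets were lower. No call was made for integrated stress response (8 higher and 11 lower of 25, adjusted p = 0.408), cholesterol synthesis (5 and 8 of 20, 0.329) or RAS-ERK feedback genes (10 and 2 of 16, 0.185). The same held for interferon response (13 and 2 of 30, or 5 and 2 adjusted over the list alone, 0.185), dendritic cell (4 and 1 of 6, 0.197), MHC class II (1 and 3 of 9, 0.723), and MHC class I genes (4 and 5 of 13, 0.764), and for nuclear oxidative phosphorylation (3 and 11 of 30, 0.394), platelet and megakaryocyte (1 and 2 of 5, 0.525) and basophil, eosinophil and mast cell genes (0 and 4 of 7, 0.192). Alternatives made calls of interferon response genes (adjusted p = 0.0107 with library totals and 0.0450 without leukaemia 2) and nuclear oxidative phosphorylation genes (0.0401 with library totals). The rotation test fry of limma, which does not set a list against other genes, also called the latter (adjusted p = 0.0488), the dendritic cell (7.27e-04), RAS-ERK (0.00730) and basophil, eosinophil and mast cell lists (0.00152). Of the smaller marker lists, 2 of 4 T cell genes were higher and 1 lower. Of the others, 1 of 2 erythroid genes (Klf1) and the 1 stromal gene, Pdgfrb (−1.74 ± 0.19), were lower, and 0 of 3 B cell and 0 of 2 NK cell genes were called by edgeR. The call of Klf1 (adjusted p = 0.0379) was lost without untreated replicate 1, 2 or 4 or doxycycline replicate 1, 3 or 4 (up to 0.126), with DESeq2 (0.0989) and with no filter (0.0659).

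**Figure D3:**
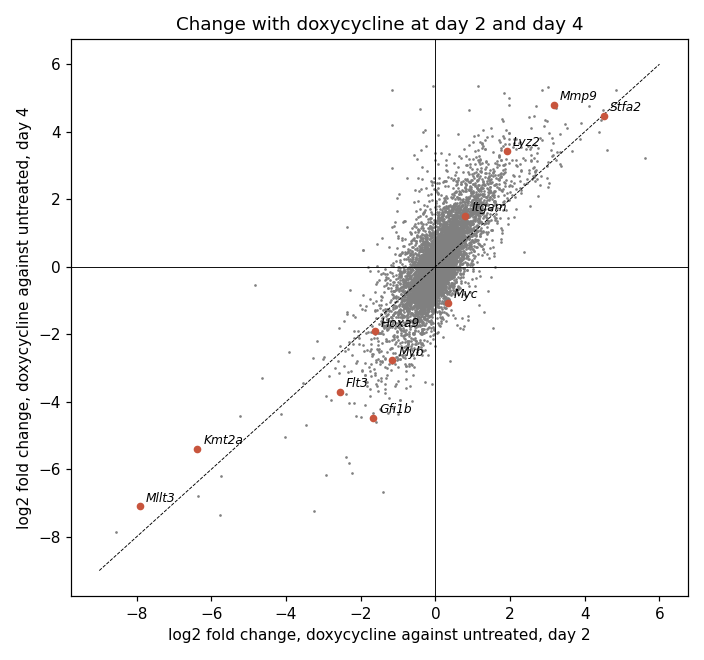
Log2 fold change with doxycycline at day 4 (vertical axis) against that at day 2 (horizontal axis), 1 point per tested gene, with 11 genes named in red and a dashed line of equal change. The correlation across genes was 0.758, and Myc lay above 0 at day 2 (0.33) and below 0 at day 4 (−1.06).

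The effects on the 2 days had much in common. Of the genes called on both days, 2060 were higher on both, beside 795 for independent lists, and 1466 were lower on both, beside 635, while 113 and 64 went opposite ways. The days share no library. Across genes, which are not independent replicates, the changes had a correlation of 0.758, and 83.0% of the genes called the same way on both days changed more at day 4.

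Testing the difference between the days itself, among genes with a mean log2 CPM of 3 or more the doxycycline effect shifted upwards by large amounts in the macrophage transcription factor gene Maf (3.38 ± 0.62), the collagenase gene Mmp8 (2.98 ± 0.79; 2.43 to 3.60 with single libraries left out), Selenop (2.69 ± 0.33) and St6gal1 (2.58 ± 0.25). Among the same genes it shifted downwards most in Angpt1 (−2.99 ± 0.40), Gfi1b (−2.80 ± 0.20), Il12a (−2.65 ± 0.42), Gem (−2.32 ± 0.68) and Kit (−2.27 ± 0.48). Myb (−1.62 ± 0.11), Myc (−1.39 ± 0.17), Meis1 (−1.04 ± 0.22), Nras (−0.44 ± 0.14) and Itgam (0.70 ± 0.15) differed between the days, and Hoxa9 (−0.30 ± 0.14, adjusted p = 0.118) did not pass, except with library totals (−0.48, adjusted p = 0.0255). The shift of Myc came from both arms: untreated cells went from 98.5 to 172 CPM and doxycycline cells from 124 to 82.2 CPM. In all, 4848 genes differed, 2181 upwards and 2667 downwards, and 4450 of them went the same way as a called effect at day 4. The day 4 effect is itself a term of the difference, so this agreement is partly built in. With library totals, 19.5% and not 45.0% of the called genes shifted upwards. The shift of Kmt2a (0.98 ± 0.36, adjusted p = 0.0438) was lost when any of 13 of the 16 libraries was left out, with an adjusted p of up to 0.0836, and with library totals (0.0868) or no filter (0.0525). The exceptions were untreated day 4 replicates 2 and 3 and doxycycline day 4 replicate 2. The Kmt2a shift came mainly from untreated cells, which lay at 11850 CPM at day 2 and 6705 CPM at day 4. Doxycycline cells lay at 143 and 159 CPM. Mllt3 (0.81 ± 0.41, adjusted p = 0.141) did not pass, but had an adjusted p of 0.0115 without untreated day 4 replicate 2. Lars2 shifted by 4.33 ± 1.41 (adjusted p = 0.0260; 0.125 with the leukaemia as a block), but by 0.65 without doxycycline day 4 replicate 1 (adjusted p = 0.0744), and its adjusted p was 0.0506 without doxycycline day 2 replicate 2.

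Among the lists, ribosome biogenesis shifted downwards in 28 of 28 genes (Dkc1, −1.29 ± 0.12; adjusted p = 1.11e-33), DNA replication in 33 of 35 (Cdc6, −0.92 ± 0.10; 1.64e-18) and cholesterol synthesis in 19 of 20 (Lss, −0.89 ± 0.13; 5.11e-11). Integrated stress response genes shifted downwards in 13 of 25 and upwards in 1 (Slc7a5, −1.45 ± 0.15; 1.35e-06), and progenitor genes in 9 of 15 and 2 (Ctsg, −1.99 ± 0.24; 6.36e-06). So did mitosis genes in 12 of 26 and 0 (Cdk1, −0.53 ± 0.10; 0.00176), stem cell genes in 5 of 10 and 0 (0.0203) and MLL fusion targets in 6 of 23 and 2 (0.0378). Upward shifts were those of lysosome genes in 21 of 27 (Psap, 2.26 ± 0.24; 1.81e-14), monocyte genes in 19 of 31 (1.54e-09), neutrophil genes in 9 of 30 (0.00521) and mitochondrial genome genes in 5 of 13 (0.0103). Between the days mt-Co2, with 100% of its windows shared, went from 731 to 198.5 CPM in untreated cells. With doxycycline it went from 837 to 428.5 CPM. The fall of genes with near copies in untreated cells, given below, thus enters the mitochondrial shift. None of these 12 calls by camera held with an estimated correlation. There the adjusted p was 0.105 for ribosome biogenesis, 0.109 for progenitor and 0.149 for monocyte genes. It was 0.215 for DNA replication, cholesterol, stress response and lysosome, 0.577 for fusion target, stem cell and mitochondrial genome and 0.653 for neutrophil and mitosis genes. With library totals the adjusted p of fusion targets and of stem cell genes was 0.124. Adjusted over the list alone, 34 replication, 20 cholesterol and 10 progenitor genes shifted downwards, and 25 lysosome and 22 monocyte genes upwards. Basophil, eosinophil and mast cell genes were lower in 4 of 7 (adjusted p = 0.0519; 0.0285 with the leukaemia as a block, 0.0361, 0.0416 and 0.0191 without leukaemia 1, 3 or 4, and 0.0115 by fry). The other 10 lists tested, which were the dendritic cell, interferon, both MHC, p53, BCL2, nuclear oxidative phosphorylation, RAS-ERK, inflammatory and platelet lists, had an adjusted p from 0.145 to 0.960. With library totals it was 0.0441 for the dendritic cell, interferon and nuclear oxidative phosphorylation lists, and by fry 0.0478 for the dendritic cell list. By fry the neutrophil and mitosis lists were not called (adjusted p = 0.116 and 0.0682).

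Untreated cells also moved between day 2 and day 4. Neutrophil maturation genes that rose included Ltf (3.59 ± 0.75; 2.77 to 4.19 with single libraries left out), Chil3 (3.17 ± 0.27), Ngp (2.60 ± 0.46) and Camp (2.60 ± 0.44), with Itgb2l (2.67 ± 0.54), and 17 of 30 neutrophil maturation genes were higher and 0 lower. Monocyte and macrophage genes were higher in 10 of 31 and lower in 0, with the complement genes C1qa (3.04 ± 0.54), C1qc (3.01 ± 0.40) and C1qb (2.37 ± 0.46). The calls of both lists, given below, did not hold with an estimated correlation (adjusted p = 0.437 each). Myc rose by 0.80 ± 0.12 (adjusted p = 5.12e-04) and Cebpa, a transcription factor of granulocyte development, by 1.07 ± 0.10 (adjusted p = 1.54e-05). Mitochondrial genome genes were lower in 9 of 13 and higher in 0, with mt-Atp8 (−2.24 ± 0.20), mt-Co2 (−1.88 ± 0.18), mt-Co3 (−1.81 ± 0.16) and mt-Nd4l (−1.77 ± 0.20). The pseudogene Rpl31-ps12 fell by 1.72 on the log2 scale.

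Between the days 2240 genes were called in untreated cells, 1243 higher and 997 lower, and 3425 (1964 and 1461) with the leukaemia as a block. The count was 1036, 963 and 1221 without leukaemia 1, 3 or 4, each under the 2240 by more than 1.5 times. Day and any batch cannot be told apart here, since all labels of day 4 carry a running number and none of day 2 does. Kmt2a (−0.82 ± 0.25, adjusted p = 0.0368) and Mllt3 (−0.83 ± 0.26, adjusted p = 0.0394) were lower in 4 of 4 leukaemias. Both calls were lost when any of the 8 libraries except untreated day 4 replicate 2 was left out, with an adjusted p of up to 0.106 and 0.111. Hoxa9 changed by −0.35 ± 0.10 (adjusted p = 0.0257), a call lost without untreated day 2 replicate 3 or 4 or untreated day 4 replicate 1 or 3 (up to 0.0774). Nras (0.08 ± 0.10), Myb (−0.06 ± 0.08), Meis1 (−0.29 ± 0.15) and Itgam (0.24 ± 0.11) did not pass, although Meis1 had an adjusted p of 0.0446 with the leukaemia as a block.

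Genes with near copies in the genome were called lower more often than higher in untreated cells at day 4, although most were not called. Of 382 pseudogenes tested, 113 were lower and 11 higher, and of 505 genes with 10% or more of their 50-base windows shared with a transcript from another chromosome, 110 were lower and 33 higher. Of 7341 genes with no shared window, 335 were lower and 836 higher. The mitochondrial genes with 90% or more of their windows shared lay between −1.88 and −1.56, and those with under 10% shared between −0.27 and −0.04, except mt-Atp8, which has no shared window and changed by −2.24. Without genes that have near copies, an alternative chosen after seeing the data, 1829 genes were called.

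**Figure D4:**
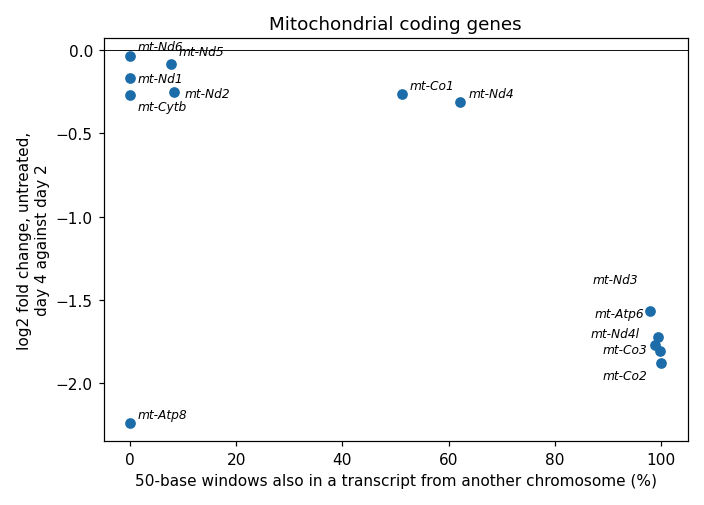
Log2 fold change of the 13 mitochondrial coding genes in untreated cells, day 4 against day 2 (vertical axis), against the percent of 50-base windows also found in a transcript from another chromosome (horizontal axis), 1 point per gene. The 5 genes with 90% or more shared lay at or below −1.56, and mt-Atp8, with none shared, lay at −2.24.

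Of the lists in untreated cells, 6 were called by camera. They were neutrophil maturation (adjusted p = 2.85e-12), monocyte and macrophage (5.17e-07) and mitochondrial genome genes (1.28e-22), and integrated stress response (6 higher and 0 lower of 25, with Ddit4 at 1.13 ± 0.18; 4.97e-04) and DNA replication genes (2 higher and 7 lower of 35; 0.00369). The last was RAS-ERK feedback (3 higher and 0 lower of 16, with Dusp6 at 0.47 ± 0.10; 0.0419, and 0.0635 and 0.0591 without leukaemia 2 or 3). None held with an estimated correlation, where the adjusted p was 0.437, 0.437, 0.0525, 0.794, 0.935 and 0.858 in the same order. Adjusted over the list alone, 20 neutrophil, 12 monocyte, 7 stress response and 4 RAS-ERK genes were higher, and 10 mitochondrial genome and 9 replication genes lower. Adjusted p was 0.136 for MLL fusion targets (1 higher and 4 lower of 23), 0.128 for progenitor genes (2 and 0 of 15), 0.442 for stem cell genes (0 and 0 of 10) and 0.972 for mitosis genes (0 and 0 of 26), and the other 13 lists tested lay between 0.136 and 0.860. Leaving out a leukaemia made calls of fusion targets (adjusted p = 0.0141 without leukaemia 2), progenitor (0.0481 and 0.0323 without 1 or 2), interferon (0.0259 without 4), inflammatory (0.00154 without 4) and basophil, eosinophil and mast cell genes (0.0289 without 1). By fry the DNA replication and RAS-ERK lists were not called (adjusted p = 0.278 and 0.104).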

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

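The tests of shared sequence, of mitochondrial transcription, of a mapping change of the vector reads, of a rise in untreated cells and of an equal effect on both days were chosen after the results were seen.

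In untreated cells, more genes with near copies were called lower than higher at day 4 against day 2, with 113 of 382 pseudogenes lower, 11 higher and most not called. A difference between the days in how reads matching several places were mapped or counted is a candidate explanation. In the doxycycline libraries, which did not define the pattern, genes with shared windows lay below those with none by a median of −0.30 (log2), and below in 4 of 4 leukaemias. Part of that gap lies between the treated and untreated libraries of day 4, where the doxycycline effect showed a gap of −0.25 to −0.15, beside −0.12 to −0.00 within day 2. For the 13 mitochondrial coding genes among those tested, lower transcription of the mitochondrial genome cannot be told apart from it by the bound chosen for the test. Those with under 10% shared had a median of −0.21 beside −1.77 for those with 90% or more, but mt-Atp8, with no shared window, changed by −2.24, so the 2 sets overlapped. By position mt-Atp8 (7766 to 7969) follows mt-Co2 (7013 to 7696, 100% shared) and overlaps mt-Atp6 (7927 to 8607, 99.5% shared). Copies without an annotated transcript were not searched, so its lack of shared windows does not show that it has no copy. The 13 genes did not fall equally. Those with 90% or more shared and mt-Atp8 changed by −2.24 to −1.56, and the others by −0.31 to −0.04. Among the latter, mt-Nd1, mt-Nd5 and mt-Nd6 changed by −0.17, −0.08 and −0.04. These values argue against an equal fall of all 13 genes as the whole cause, while an unequal fall stays open. Day and batch coincide, and a biological difference between the days was not tested.

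Kmt2a and Mllt3 were lower in untreated cells at day 4, with Kmt2a changes of −1.14, −0.39, −1.71 and −0.57 (log2) in leukaemias 1 to 4. Cells in the state of doxycycline day 4 mixed into those libraries are argued against. Kmt2a moved 23.8% to 70.4% of the way to the doxycycline day 4 level. The 342 genes that rise 4-fold or more by then moved by a median of 9.29% at most, and Lyz2 by 3.20% to 8.39%. Cells exposed for a shorter time are not covered by these shares. With doxycycline at day 2 Kmt2a already lay at 143 CPM, while Lyz2 lay at 6219 CPM beside 37480 CPM at day 4. A common change in mapping as the whole cause is argued against only weakly. The Kmt2a changes had a range of 1.32 beside 0.46 for the levels in the untreated day 2 libraries. The first is a range of differences between 2 libraries and the second of single libraries, so the 2 ranges are not like for like. Loss of vector expression or of cells that carry it stays open and was not tested.

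Integrated stress response and cholesterol synthesis genes were higher with doxycycline at day 2 and not called at day 4. A rise in untreated cells by day 4 as the whole cause is argued against by the doxycycline libraries. Between the days the members had a median change of −0.46 in these (−0.31 for stress response and −0.61 for cholesterol synthesis genes). There 12 of 25 stress response genes were lower and 3 higher, and 19 of 20 cholesterol genes lower and 0 higher. In untreated cells 6 of 25 stress response genes were higher and 0 lower (median 0.29), and that list call did not hold with an estimated correlation (adjusted p = 0.794). So a rise in untreated cells as part of the cause stays open for the stress response genes. Of 20 cholesterol genes, 2 were higher and 1 lower in untreated cells (median −0.03). A batch that coincides with the day could shift both arms, so the argument from the doxycycline libraries holds only without such a batch. An equal effect of doxycycline on both days is argued against by the test of the difference (fry, a rotation test of limma: adjusted p = 2.96e-04 and 1.55e-04, with 7.72e-05 the higher value before adjustment). The 2 lists were picked for their unlike calls on the 2 days in the same libraries, so this test is not separate support. The adjustment ran over all lists tested. Camera with an estimated correlation called neither list, with an adjusted p of 0.215 for both in the difference and of 0.208 and 0.193 at day 2. Loss of MLL-AF9 and an action of doxycycline itself cannot be told apart, since none of the 4 groups holds cells with doxycycline in which the fusion stays on.

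Other divisions of the same libraries were tested for the 4 counts of called genes. At day 2 the real division called 4380 genes and was 1 of 35 with as many, the highest other calling 619 in a division that kept some pairs of a leukaemia together. At day 4 it called 8723 genes (1 of 35, highest other 0), and in untreated cells between the days 2240 (1 of 35, highest other 15). For the difference between the days it called 4848 genes, 1 of 100 draws with as many, and the highest other called 1855. Since the leukaemias pair the libraries, the real division is to be set against those that part all pairs. These were 8 in each of the 3 comparisons of 2 groups, too few for a share under 0.05, and the highest other among them called 0 genes. The draws for the difference were not sorted by pairs.

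Single libraries stood apart from the other 3 of their group in 16 of 196 checks, where chance gives about 1 in 20, or 9.8. Lars2 lay at 5068 CPM in doxycycline day 4 replicate 1 beside 88.8 to 119 in the others, and at 134.1 in doxycycline day 2 replicate 4 beside 75.2 to 82.7. Mmp8 lay at 547.0 in doxycycline day 4 replicate 1 (others 213 to 266) and at 27.7 in untreated day 2 replicate 3 (others 9.09 to 10.04). Doxycycline day 2 replicate 4 stood apart in 5 more genes: Ccl6 at 129.5 (others 21.4 to 38.5), Il12a at 36.8 (17.6 to 20.9), Gem at 148.5 (48.8 to 52.7), Kit at 39.1 (15.3 to 17.8) and mt-Co3 at 416.4 CPM (713 to 764). Also low in that library were mt-Co2 at 515 (888 to 978), mt-Atp8 at 72.0 (146 to 163) and mt-Nd3 at 47.9 CPM (87.7 to 97.6). There mt-Cytb, with no shared window, lay at 3866 CPM (4007 to 4180). These mitochondrial genes thus varied within day 2 as well as between the days. Kit also lay at 9.88 in doxycycline day 4 replicate 4 (3.44 to 4.16), Gem at 62.0 in untreated day 2 replicate 4 (18.8 to 26.0) and Ltf at 70.2 in doxycycline day 2 replicate 1 (15.4 to 22.5). Untreated day 2 replicate 2 had Hpgd at 227.0 (464 to 472) and Ccl6 at 6.64 (10.1 to 10.5). S100a9 lay at 209.2 in untreated day 2 replicate 1 (126 to 140) and C5ar1 at 23.2 CPM in untreated day 4 replicate 1 (12.1 to 14.0).

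The effect of doxycycline differed between the days, by the test of the difference, in 4848 genes. Among named genes the log2 differences, day 4 minus day 2, were 0.98 for Kmt2a, −0.44 for Nras, −1.04 for Meis1, −1.62 for Myb, −1.39 for Myc and 0.70 for Itgam. They were 4.33 for Lars2, 3.38 for Maf, 2.98 for Mmp8, 2.69 for Selenop, 2.58 for St6gal1, −2.99 for Angpt1, −2.80 for Gfi1b, −2.65 for Il12a, −2.32 for Gem and −2.27 for Kit. The calls of Kmt2a and Lars2 were lost without single libraries, with an adjusted p of 0.0694 and 0.0744 without doxycycline day 4 replicate 1.

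Differences between the days were also found for 12 lists, none of which held with an estimated correlation. The median log2 differences were −0.25 for MLL fusion targets, −1.06 for stem cell, −0.95 for granulocyte-monocyte progenitor, −0.35 for mitosis, −0.55 for DNA replication, −0.84 for ribosome biogenesis, −0.49 for integrated stress response and −0.55 for cholesterol synthesis genes. They were 0.72 for neutrophil maturation, 1.14 for monocyte and macrophage, 0.34 for mitochondrial genome and 0.76 for lysosome genes.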

How the results depend on the processing

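The alternative without genes that have near copies was chosen after the data were seen. It called 4233, 8031, 4487 and 1829 genes at day 2, at day 4, in the difference between the days and in untreated cells. Counts of called genes stayed within 1.5 times of 4380, 8723, 4848 and 2240 under DESeq2, other size factors, library totals, both filters, only the groups compared and limma-voom. A test against a minimum change of 1.5-fold called 405, 2741, 333 and 63 genes, since it asks for a larger change. With the leukaemia as a replicate block the counts were 5435, 9330, 5968 and 3425, and the last exceeded 2240 by more than 1.5 times. The block changed 1 list call, that of basophil, eosinophil and mast cell genes in the difference between the days, and among named genes those of Lars2 (0.0533 and 0.125), Meis1 in untreated cells (0.0446) and Ighm at day 4 (0.0197). With single libraries or whole leukaemias left out, the count in untreated cells ranged from 963 to 2219, where fewer libraries were fitted. With an estimated correlation, 1, 1, 0 and 0 lists were called in place of 15, 13, 12 and 6. By fry, which does not set a list against other genes, 12, 17, 12 and 4 lists were called. Nras changed sign at day 4 with library totals (−0.0211), where all genes shifted downwards, and in untreated cells its change ranged from −0.0126 to 0.160 over left-out libraries; the cause of the latter was not tested. With library totals, 7061 of the 8723 genes called at day 4 were called the same way and 134 the opposite way. Of 313 comparisons of a named gene, 250 kept their call whichever single library was left out and 50 lost it at least once. Small changes can be missed, as 32 of 50 simulated 1.5-fold changes were found at day 2, and the part of depth in this was not tested. The simulation changed 200 of 13273 genes, so its rates need not hold where 4380 or 8723 genes were called.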

Other observations

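Genes of antigen presentation went both ways at day 4. Of 9 MHC class II genes, Cd74 rose by 2.40 ± 0.51 (SE, n = 4 libraries per group; 2.02 to 3.29 with single libraries left out), while H2-Ob (−1.61 ± 0.34) and H2-Oa (−0.94 ± 0.16), which encode a modulator of peptide loading, fell. Of 13 MHC class I genes, 4 were higher, among them B2m (0.72 ± 0.11), and 5 lower, among them the peptide transporter gene Tap2, which fell by 1.06 on the log2 scale. Of 4 T cell genes, Il7r, the interleukin 7 receptor gene, rose by 3.07 ± 0.38 and Lck fell by 2.19 on the log2 scale. The MHC lists were not called as a whole, and the T cell list had too few tested members for a list test.

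A hypothesis was that untreated cells move between the days part of the way along the change that doxycycline brings. Over 11102 genes outside the lists with under 10% of windows shared, the untreated change of each leukaemia was set against the day 2 effect of doxycycline in the other 3, so that no library entered both. The correlations across genes, which are not independent replicates, were 0.446, 0.275, 0.359 and 0.108 in leukaemias 1 to 4. The lowest, 0.108, was barely above the bound of 0.1 set for the test, and the rank correlation of leukaemia 4 was 0.0481. The values are consistent with such a movement in leukaemias 1 to 3 and leave it open in leukaemia 4, and a batch that coincides with the day may contribute.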
